A study of Saccharomyces cerevisiae with 2 samples.

How the data were processed

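Total RNA of 1 wild-type culture (BY4741) and 1 mtf1 deletion culture, both in stationary phase in synthetic dextrose medium, was labelled with Cy3 and hybridised to a yeast expression array, per the labels' protocols. Labelling used an oligo-dT primer with T7 amplification, per the labels' protocols. Both arrays were on the same slide and in the same scan, so slide and scan do not separate the groups, and no other batch could be tested with 1 array per group. The groups were taken from the genotype given in the labels.

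The files hold 1-colour intensity values per spot, which Agilent Feature Extraction 10.7.3.1 made with its GE1 protocol, per the file headers. The submitters' processing notes name the same software. The processed intensity has the background subtracted and spatial trends removed, with a surrogate value where a spot is too close to background, and it is not normalized between arrays, per the file headers. The same deposited files give raw mean and local background intensity and flags of 0 or 1 for other spot properties. The deposited series table holds log2 values per gene name in 6224 rows, all matched to a gene name of the spots. Set against the log2 processed intensity, these log2 values correlated with r = 0.998 in the wild type and r = 0.999 in the mtf1 deletion across genes, and 98.6% and 98.4% of them lay within 0.05 of 1 constant per array, so their scale is log2 with 1 factor per array. Their column medians were -1.76 and -1.75, with no centring per gene seen. How the authors chose that factor stays unknown.

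Per array, the 75th percentile of the processed signal over gene spots was 3258 units in the wild type and 4003 units in the mtf1 deletion. The log2 processed signal minus the log2 of this percentile was the level of a spot. Control spots were left out, and so were spots that carried an outlier flag on either array (169 gene spots in the wild type and 169 in the mtf1 deletion). Spots of a probe were averaged, then probes of a gene. Only 28 genes had over 1 probe, with a median range of 0.15 between their log2 ratios, and in 1 of them the probes lay on opposite sides of 0. The flags left no spot for 8 of 6227 genes, among them the list members QCR6, PYC1, YDJ1 and TDH1, and SPG1 and HSP150 were not analysed here. Saturated spots were kept. A gene counted as well above background when most spots of any of its probes carried that flag. This held for 5655 genes on both arrays, 252 in the wild type alone, 5 in the mtf1 deletion alone and 307 on neither. The imbalance goes with a noisier background of the mtf1 deletion array. Raw signals of negative control spots had an SD of 16.0 units there and 4.85 units in the wild type. Their raw medians were close, at 41.5 and 40.3 units. The median processed signals of these spots were 8.74 and 2.91 units. For a gene well above background on 1 array, the dim level was set to the higher of its own and the lowest level among probes well above background on that array, and the ratio is a bound. A gene saturated on its brighter array, by most of its spots, is also given as a bound. Genes saturated on both arrays stayed in the counts and list medians, and the alternative without saturated probes removes them. That rule on most spots, and the order in which current and older gene names were matched, were settled after the values had been seen.

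Gene names were taken by systematic name from a RefSeq table of assembly R64, which held 5730 of 6219 names, and the array's own name was kept for the other 489. Probe positions are those of the files, on build sacCer1, per the file headers, and the table gave names and neighbours but no positions.

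Genes were counted at a 2-fold threshold, with bounds counted where they passed it. For each of 36 gene lists and each chromosome, the median log2 ratio over genes well above background on both arrays was ranked among the medians of 10000 random lists of the same size, drawn to match the mean level in 20 bins. This describes the arrays and is not a test across cultures. Lists, thresholds and the rule for named genes were fixed before the data were examined. The rule named MTF1, its neighbours and the strain markers, the 15 highest and 15 lowest ratios among named genes well above background on both arrays with every probe on the same side of 0, the 5 highest and 5 lowest bounds, the 4 members of each list with the largest ratios, and all core mitochondrial genes. CIT2, ICL1, PDR5, RPO41 and Q0017 lie outside this rule and were chosen after their values were seen, as were the further genes and lists of the closing section. 1 of the genes that the rule names is not reported here.

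The alternatives were normexp background correction (offset 50), quantile normalization, median centring, intensity-dependent loess (span 0.4), no filter on dim probes, only genes well above background on both arrays, outlier-flagged spots kept, saturated probes left out, the brightest probe per gene, thresholds of 1.5-fold and 3-fold, every probe past the threshold, the deposited series values, and random lists not matched on level. Scaling on 6 spike-in probes and a count with every spot past the threshold were added after seeing the data. The gene and list steps were tested on simulated data made from the wild-type array with spot noise only. In 6223 genes, all 50 genes at each log2 change of -2, -1.5, 1.5 and 2 passed the threshold (100% at each size), and 0 of 5983 unchanged genes did. These changes lay well past the threshold for such small noise, so the outcome checks the computation and not its power between cultures. The simulated array kept the wild type's background and saturation flags, so the rules for bounds were not exercised. Of 200 unshifted lists, 4.5% lay outside the central 95%, in 5911 genes. Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6, and in R 4.3.3 with limma 3.58.1.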

Results

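RNA levels of the budding yeast Saccharomyces cerevisiae were measured on 1-colour Agilent expression arrays in 2 stationary-phase cultures grown in synthetic medium with dextrose. The wild type was BY4741, a laboratory haploid strain, and the other culture carried a deletion of MTF1, which encodes the specificity factor of the mitochondrial RNA polymerase. There was 1 array per group, so no value below has a replicate check, no test was made between the strains, and the number of arrays limits the precision. The SD given with some ratios is the technical spread of the log2 ratio between the 2 or 3 spots of a probe. Each spot was paired with the spot at the same position on the other array. Each array held 15208 gene spots from 6256 probes for 6227 systematic names. In the wild type 95.4% of the gene spots were well above background, against 91.5% in the mtf1 deletion, and the lowest probe well above background had a processed signal of 10.1 units in the wild type and 39.8 units in the mtf1 deletion. Ratios are log2 values of the mtf1 deletion minus the wild type. A gene that was not well above background on 1 of the arrays, or saturated on the brighter one, is given as a bound with the words at least.

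The deleted gene was read first as a check of the labels. The MTF1 probe (YMR228W, chromosome XIII, positions 725395 to 725454 on build sacCer1) had a processed signal of 418 units in the wild type and 8.52 units, not well above background, in the mtf1 deletion, which is at least 12.9-fold lower. HIS3, LEU2, MET17 (also called MET15) and URA3, the marker genes that BY4741 lacks, were not well above background on either array. LYS2, which BY4741 keeps, had 391 units in the wild type and 951 units in the mtf1 deletion, a log2 ratio of 1.01 with a spot SD of 0.39, under 2-fold with normexp and quantile normalization. The neighbours of MTF1 were both brighter in the mtf1 deletion. TAF7 (YMR227C, probe at positions 722686 to 722745 of chromosome XIII), which encodes a subunit of the general transcription factor TFIID, was 5.17-fold higher, with 2692 units in the wild type and 17108 units in the mtf1 deletion. RRP5 (YMR229C, probe at positions 726009 to 726068), which encodes a ribosomal RNA processing factor, was 1.94-fold higher.

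The comparison of the strains addressed how nuclear and mitochondrial transcripts differ in stationary phase when the mitochondrial transcription factor is missing. Across the 5655 genes well above background on both arrays, the log2 ratio had a median of -0.06 and an SD of 0.79, and the levels of the 2 arrays correlated across genes with r = 0.94. Genes are not independent replicates. Of 5912 genes well above background on at least 1 array, 558 were at least 2-fold higher in the mtf1 deletion and 463 at least 2-fold lower. Of these, 5 of the higher and 26 of the lower genes rested on a bound. Genes known only by a systematic name made up 87 of the higher and 47 of the lower genes. The median spot SD of the log2 ratio was 0.05, far below the 2-fold threshold, but it holds no variation between cultures.

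The gene with the highest ratio was HXT2, which encodes a high-affinity glucose transporter, at 28.4-fold higher in the mtf1 deletion (250 units in the wild type and 8721 in the mtf1 deletion, log2 ratio 4.83, spot SD 0.02). SET6 was 12.7-fold higher from a low signal of 22.6 units. LAF1 (YMR102C) was 10.6-fold higher, SNO1, of pyridoxine metabolism, 10.6-fold, the ferric reductase homologue FRE5 9.72-fold, YRO2 9.69-fold and the phosphate-regulated PHM6 9.18-fold. HMS1 was 8.83-fold higher, the multidrug transporter AQR1 8.73-fold, SKG3 8.42-fold, the glycerol phosphatase GPP1 7.80-fold, the acidic amino acid permease DIP5 7.76-fold, the nucleolar protein gene NSR1 7.50-fold and the chitin synthase CHS1 7.46-fold. The carnitine acetyltransferase YAT1, saturated in the mtf1 deletion, was at least 8.69-fold higher. With normexp background correction the dimmer genes of this group had smaller log2 ratios, 2.13 for SET6, 2.46 for SNO1 and 2.55 for FRE5.

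Among genes well above background on both arrays, the lowest ratios after the mitochondrial OLI1 belonged to ADH2, the glucose-repressed alcohol dehydrogenase, at 11.9-fold lower in the mtf1 deletion (spot SD of the log2 ratio 0.27), and FBP1, the gluconeogenic fructose bisphosphatase, at 11.5-fold lower. The oligopeptide transporter OPT2 was 9.41-fold lower, the S-methylmethionine permease MMP1 8.25-fold, EEB1, of fatty acid ethyl ester synthesis, 6.84-fold, and GCV1, of the glycine cleavage system, 6.66-fold. The mitochondrial succinate and fumarate carrier SFC1 was 6.45-fold lower, the amino acid permease AGP3 5.97-fold and the fatty acid desaturase OLE1 4.99-fold. HBN1 was 4.18-fold lower, OYE3 4.15-fold, MIC60, of the mitochondrial contact site complex, 4.05-fold, and NDJ1 4.02-fold. JIP3, a reading frame that the array annotation calls dubious, was 5.28-fold lower. The ADH2 signal of 58.4 units in the mtf1 deletion was below the brightest negative control spot there at 87.1 units. The NDJ1 signal of 60.8 units was below it too. With normexp background correction ADH2 had a log2 ratio of -2.57, behind FBP1, EEB1, MMP1, GCV1 and OPT2. OPT2 then had -2.60 and NDJ1 -1.30. The 5 genes well above background in the mtf1 deletion alone with the highest bounds were dim: YPR014C was at least 5.48-fold higher, YMR306C-A 4.46-fold, YDL011C 4.15-fold, PRM10 3.94-fold and YHR212W-A 2.14-fold. These 5 were all under 2-fold with normexp background correction, where YPR014C had a log2 ratio of 0.66.

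**Figure D1:**
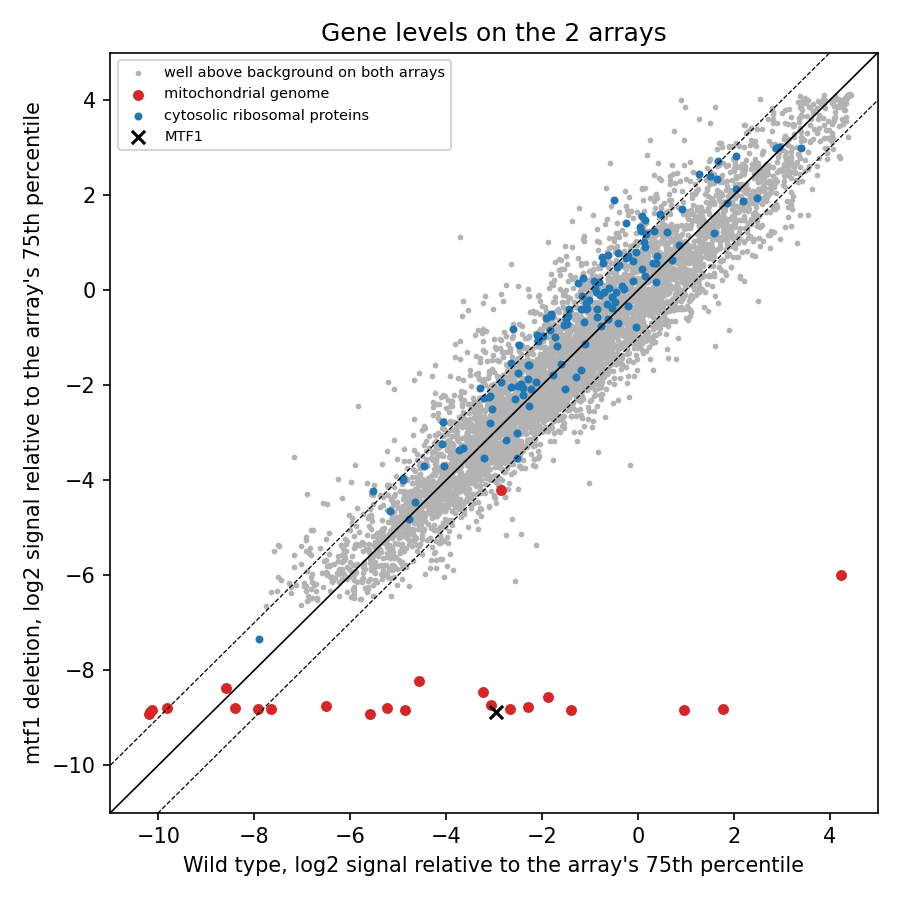
Each point is a gene, with its log2 signal relative to the array's 75th percentile in the wild type (horizontal axis) and in the mtf1 deletion (vertical axis). The solid line marks equal levels and the dashed lines a 2-fold difference. Most genes of the mitochondrial genome (red) and MTF1 (cross) lie at the bottom of the plot, with Q0017 and OLI1 higher at 218 and 62.7 units in the mtf1 deletion, and most cytosolic ribosomal protein genes (blue) lie above the line, at a median log2 ratio of 0.69.

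Transcripts of the mitochondrial genome were near or below background in the mtf1 deletion. Of 8 protein-coding genes of the core list, 7 were at least 2-fold lower and none higher. OLI1, which encodes a subunit of the membrane ring of ATP synthase, was saturated at 61137 units in the wild type and had 62.7 units in the mtf1 deletion, at least 1200-fold lower. It was the only core gene still well above background there, though below the brightest negative control spot of that array at 87.1 units. COB, encoding cytochrome b, had 6322 units in the wild type and 8.81 units in the mtf1 deletion, at least 195-fold lower. ATP6 was at least 27.5-fold lower, COX1 at least 20.6-fold, COX3 at least 15.9-fold, ATP8 at least 12.1-fold and COX2 at least 3.45-fold. VAR1, the mitochondrial ribosomal protein gene, had only 16.4 units in the wild type and allowed no bound. The median log2 ratio of the core genes with bounds was -4.18. With normexp background correction it was -2.83 and 6 core genes were at least 2-fold lower, with COX2 at -0.995. The log2 ratios of the other 6 were smaller in size with normexp too, such as -2.27 for ATP8.

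Among all 23 mitochondrial reading frames on the array, 14 were at least 2-fold lower in the mtf1 deletion, 2 lay between and 7 were not well above background on either array. AI5_ALPHA and AI2, intron-encoded frames of COX1, were at least 346-fold and at least 38.5-fold lower. With normexp background correction their log2 bounds shrank from -8.44 to -6.97 and from -5.27 to -3.87. Besides OLI1, Q0017, a reading frame that the array annotation calls dubious, alone was well above background on both arrays, with 450 units in the wild type and 218 in the mtf1 deletion, a log2 ratio of -1.34. Cross-hybridisation of its probe was not checked. The labels describe labelling with an oligo-dT primer, and mitochondrial messengers of this yeast lack long poly(A) tails, so their wild-type signals cannot be read as relative amounts.

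**Figure D2:**
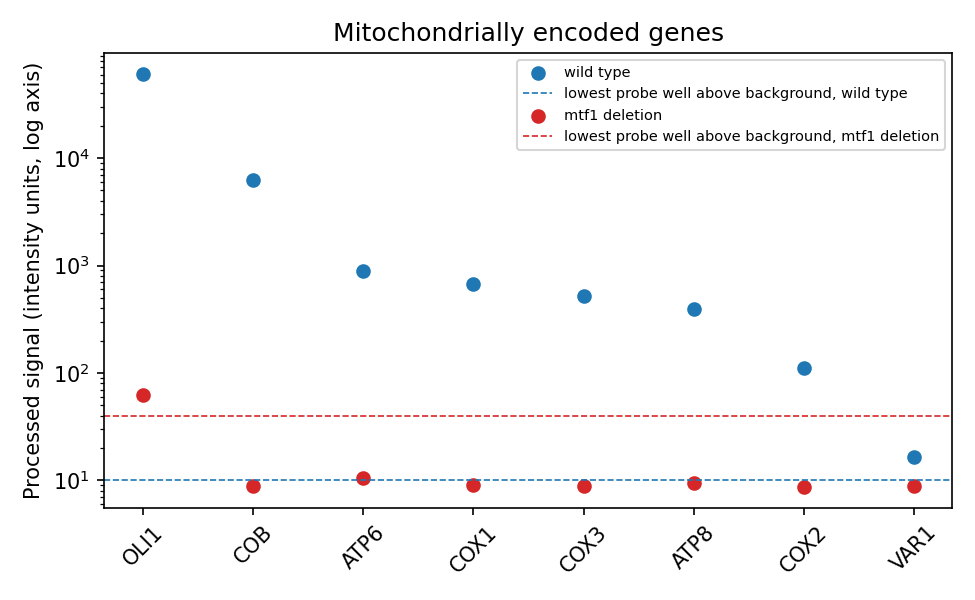
Processed signal (intensity units, log axis) of the 8 core mitochondrially encoded genes in the wild type (blue) and the mtf1 deletion (red), 1 array each. Dashed lines give the lowest probe well above background on each array, 10.1 and 39.8 units, and OLI1 alone lies above the line of the mtf1 deletion there.

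Nuclear genes of the respiratory chain had lower signals in the mtf1 deletion as a group. The list of complexes II to IV and cytochrome c had a median log2 ratio of -0.74, lower than all but 2 of 10000 random lists of the same size and signal level, as a description of these arrays. Of its 21 measured genes, 6 were at least 2-fold lower and none at least 2-fold higher. COX5A had a log2 ratio of -1.49, QCR2 -1.49, SDH3 -1.37 and COX8 -1.22. The nuclear ATP synthase genes had a median of -0.71, with 26 of 10000 random lists below it. All 15 had negative ratios and 6 were at least 2-fold lower, among them ATP20 at -1.66, TIM11 at -1.32 and ATP16 at -1.27, and ATP5 was 2.83-fold lower.

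The lists of the TCA cycle, mitochondrial ribosomal proteins, mitochondrial DNA maintenance, import and the retrograde response lay inside the central 95% of random lists. The 13 TCA cycle genes had a median log2 ratio of -0.21, which was 0.00 with intensity-dependent normalization. CIT3 was higher at 1.62, and LSC2 at -1.29, LPD1 at -1.11 and KGD1 at -1.05 were lower, the last pair of these at under 2-fold with that normalization. The 70 mitochondrial ribosomal protein genes had a median of -0.05, with 3 at least 2-fold lower, namely MRPL50 at -1.25, MRP51 at -1.11 and MRPL7 at -1.08. Intensity-dependent normalization turned the sign of that median. The 27 genes of mitochondrial DNA maintenance and expression had a median of -0.15. Of these, RPM2, the protein subunit of mitochondrial RNase P, was higher at 2.14, RIM1, a single-stranded DNA binding protein, was lower at -1.22, and RPO41, the mitochondrial RNA polymerase that works with Mtf1, had 0.74. The 29 import genes had a median of -0.20, with TIM50 at -1.28, PAM17 at -1.08 and TOM70 at -1.02 lower. PAM17 was under 2-fold with normexp, and TOM70 with normexp, intensity-dependent normalization and spike-in scaling. The 8 measured retrograde response targets, which respond to mitochondrial dysfunction in growing cells, had a median of 0.09. PDH1 was higher at 1.26, IDH2 had 0.82 and DLD3 0.73. CIT2, the usual reporter of that response, was saturated on both arrays and gave no usable ratio. Its saturated value of -0.31 is still among the 8 that made the median.

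Genes of fatty acid breakdown were lower and those of other carbon pathways were mixed. The 15 genes of peroxisomal beta-oxidation had a median log2 ratio of -1.15, below all 10000 random lists, with 10 at least 2-fold lower and none at least 2-fold higher. The peroxisomal catalase CTA1 had -1.86, FOX2 -1.84, the thiolase POT1 -1.66 and the acyl-CoA oxidase POX1 -1.43. In the glyoxylate and gluconeogenesis list of 16 genes, 4 were at least 2-fold lower (ADH2, FBP1, SFC1 and ICL1) and YAT1 higher, with a median of -0.04 whose sign turned with intensity-dependent normalization. The 16 measured glycolysis and fermentation genes had a median of -0.46, with 404 of 10000 random lists below it. In that list the hexokinase HXK2 was higher at 2.06, ENO1 was lower at -1.80, and TDH3 had -0.87 and TDH2 -0.81. The 16 hexose transporters and sensors measured on both arrays had a median of 0.06, whose sign turned with normexp and with no filter on dim probes. Of 17 members, 4 were at least 2-fold higher, among them HXT2, HXT3 at 1.43 and HXT5 at 1.06, and HXT9 was lower at -1.06, though under 2-fold with normexp.

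Genes of cytosolic ribosomes were higher in the mtf1 deletion as a group. The 135 measured ribosomal protein genes had a median log2 ratio of 0.69, above all 10000 random lists. Of these, 33 were at least 2-fold higher, 1 was at least 2-fold lower and 114 had positive ratios. RPS27B had 2.41, RPL33B 1.79, RPS3 1.67 and RPL36B 1.49. Many of these genes have a near-identical copy, and the ratios of single copies are uncertain. The ribosome biogenesis list had a median of 0.65 over 51 genes, also above all 10000 random lists. In it 10 genes were at least 2-fold higher and none at least 2-fold lower. NSR1 led it, followed by DBP2 at 2.17, CIC1 at 2.06 and NOP1, the nucleolar methyltransferase fibrillarin, at 1.56. The 44 amino acid biosynthesis genes under Gcn4 control had a median of 0.56, above all 10000 random lists. Of these, 11 were at least 2-fold higher and 1 at least 2-fold lower. TRP4 had 1.75, ILV5 1.46 and ILV2 1.24.

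Purine synthesis and proteasome genes were lower. The 15 genes of purine and one-carbon synthesis had a median log2 ratio of -1.01, below all 10000 random lists, with 8 at least 2-fold lower and none at least 2-fold higher. GCV1 was followed by GCV3 at -1.84, ADE2 at -1.46 and ADE17 at -1.41. All but 1 of the 34 proteasome genes had negative ratios, with a median of -0.74, below all 10000 random lists. Of these, 8 were at least 2-fold lower, among them RPT5 at -1.36, PUP2 at -1.32, RPN10 at -1.13 and RPN1 at -1.10. The 17 cyclin and S-phase genes measured on both arrays had a median of -0.23, inside the range of random lists, with CDC20 higher at 1.85, and SWI5 at -0.76 and CLN2 at -0.74.

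Drug resistance and iron genes were higher. The 15 measured targets of the pleiotropic drug resistance factors had a median log2 ratio of 0.95, with 9997 of 10000 random lists below it. Of 16 members, 7 were at least 2-fold higher and 2 at least 2-fold lower. After LAF1 came YGR035C at 2.67, the transcription factor PDR3 at 1.46 and the lipid transfer protein PDR16 at 1.26, and the transporter PDR5 had 1.06. The iron regulon of 26 genes, which serves iron uptake and reuse, had a median of 0.71, with 9999 of 10000 random lists below it, 10 genes at least 2-fold higher and none at least 2-fold lower. After FRE5 came the iron permease FTR1 at 1.74, the cell wall mannoprotein FIT3, saturated in the mtf1 deletion, at 1.49 or more, and FRE3 at 1.47.

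The other nutrient lists had single members far from their median. The thiamine and pyridoxine list had a median log2 ratio of -0.51 over 21 genes, with 62 of 10000 random lists below it. It held 7 genes at least 2-fold lower, such as SNZ2 at -1.32 and SNZ3 at -1.29. SNZ2 and SNZ3 are near-identical copies and cannot be separated by these probes with certainty. The list also held 2 genes at least 2-fold higher, SNO1 and its partner SNZ1 at 2.61. The 15 phosphate starvation genes had a median of 0.07, with PHM6, GIT1 at 2.78, PHO89 at 2.34 and PHM8 at 1.56 higher. The sulfur and methionine list had a median of -0.07 over 22 genes, with MMP1 lower and MET13 higher at 1.59. The nitrogen catabolite list had -0.08 over 20 genes, with DAL2 lower at -1.64, and MEP1 at 1.42 and PUT1 at 1.16 higher. The signs of these last 2 medians turned with intensity-dependent normalization. The 25 ergosterol genes had a median of -0.12, with ERG20 at -1.30, ERG10 at -1.18 and ERG9 at -1.14 lower. The hypoxic and heme-repressed list had -0.02 over 14 genes, positive with no filter on dim probes, with the sterol importer AUS1 higher at 2.77, and OLE1 and HEM13, at -1.19, lower.

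Stress genes lay inside the range of random lists, with members on both sides. The 36 general stress genes had a median log2 ratio of -0.29, with 8 at least 2-fold lower and 3 at least 2-fold higher. The lower ones included RTN2 at -1.93, GAD1 at -1.87, the cytosolic catalase CTT1 at -1.60 and SOL4 at -1.57. The 23 heat shock and chaperone genes had a median of -0.27, which was 0.17 without saturated probes. HSP12 was lower at -1.89, SSA3 lower at -1.58, SSA2 higher at 1.55, and HSP78, saturated in the mtf1 deletion, had 0.45 or more. The 22 oxidative stress genes had a median of -0.37, with OYE3, TSA2 at -1.91 and CTA1 lower and ATR1 higher at 2.33. Without saturated probes that median was -0.63 and lay below the central 95% of random lists. The 11 endoplasmic reticulum folding genes had a median of 0.04, with LHS1 at 1.09 and EUG1 at 1.06, the latter under 2-fold with normexp. The 35 autophagy genes measured on both arrays had -0.14, with ATG41 higher at 1.93 and ATG15 at -1.57 and ATG17 at -1.30 lower. The 12 cell wall genes had -0.27, with TIP1 at -1.24, PIR1 at -1.16 and CWP2 at -1.13 lower.

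Mating-type and meiotic genes were read as markers of other cell states. The 6 measured genes specific to MATa cells, the mating type of BY4741, had a median log2 ratio of -0.89, with 18 of 10000 random lists below it. ASG7 had -1.06, MFA2 -1.01, BAR1 -0.98 and MFA1 -0.80. MFA2 was under 2-fold in 5 alternatives. Of the 4 MATalpha genes, 2 were measured on both arrays, STE3 at 0.48 and SAG1 at -0.25, with a median of 0.12 that turned to -0.27 with no filter on dim probes. The alpha-factor gene MF(ALPHA)1 was well above background in the wild type alone and at least 2.14-fold lower in the mtf1 deletion, under 2-fold with normexp and the deposited series values. The 10 measured meiosis and sporulation genes had a median of -0.16, with DMC1 at -1.46.

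**Figure D3:**
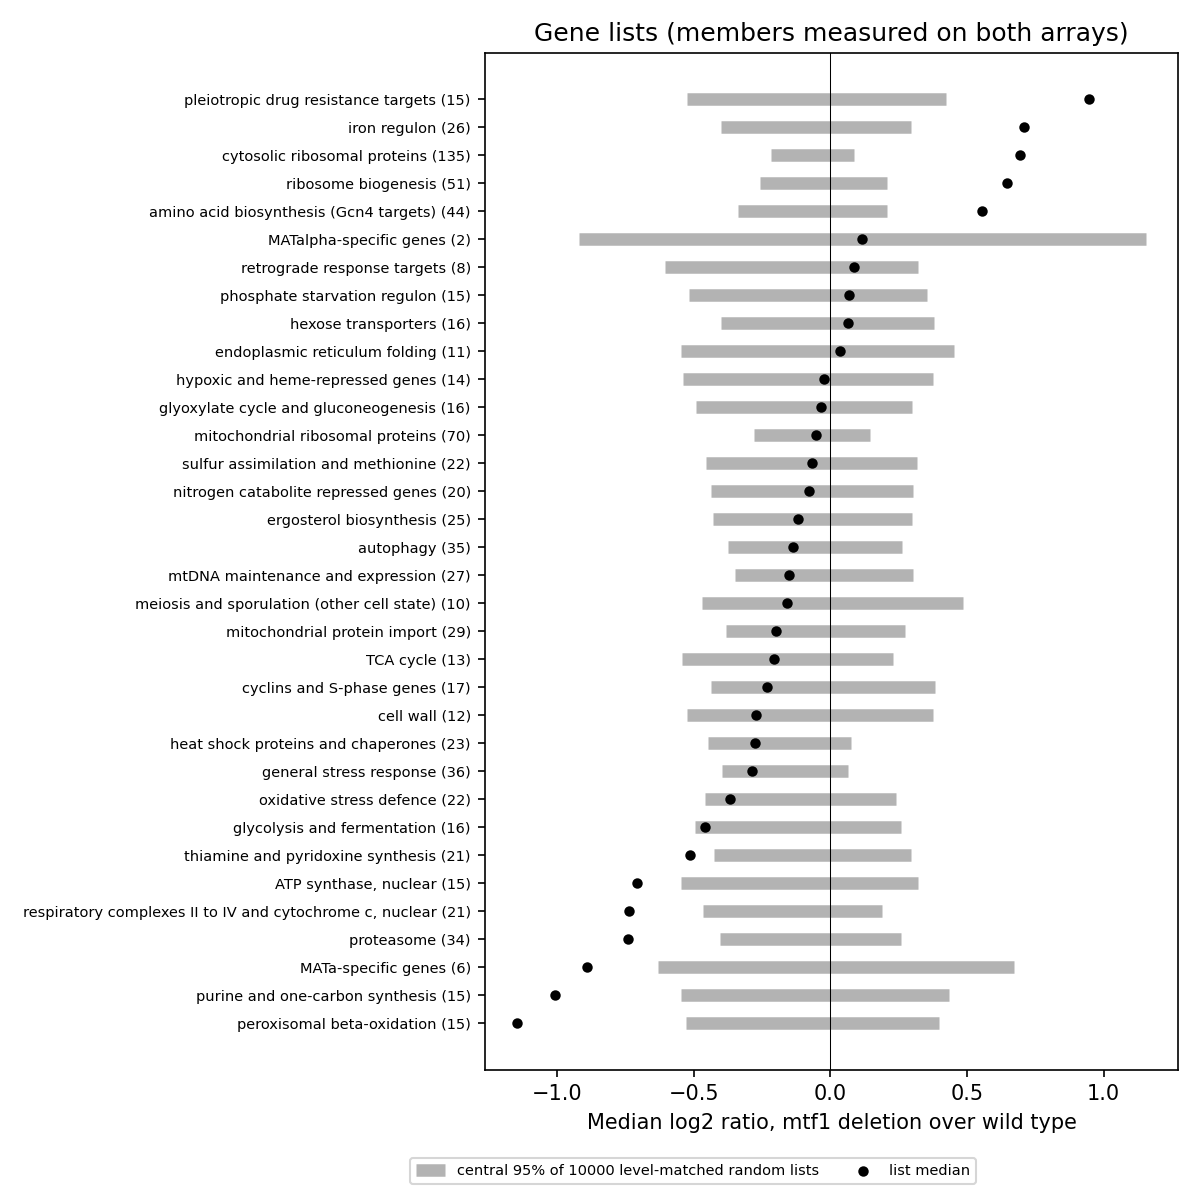
Median log2 ratio (mtf1 deletion over wild type) of each nuclear gene list, over the members well above background on both arrays (number in brackets). Grey bars span the central 95% of 10000 random lists of the same size and signal level, and 5 lists lie above their bar, led by the drug resistance targets at 0.95, and 7 below, led by peroxisomal beta-oxidation at -1.15.

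The median log2 ratio per chromosome ran from -0.38 on chromosome VI (113 genes) to 0.03 on chromosome XIV (379 genes). Chromosome VI lay below all 10000 random lists of its size and signal level. Chromosome III, with a median of -0.23 over 147 genes, had 70 random lists below it, and chromosome IX, at -0.18 over 198 genes, had 241. Chromosome XIV had 9788 below it, and the remaining chromosomes lay within the central 95%.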

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

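Values here are log2 ratios or counts. All 13 gene lists outside the central 95% of random lists stayed outside it, on the same side, in each alternative run on the values with 2000 random lists, except that all mitochondrial frames could not be ranked without saturated probes, which left 1 measured gene. None of their medians turned sign. Random lists not matched on level put the glycolysis list below the range too. Counts of 2-fold genes stayed within 1.5 times in every alternative except the thresholds: at 1.5-fold 1143 genes were higher and 1284 lower, at 3-fold 193 and 78. Of 151 named genes past 2-fold, those chosen after their values were seen included, 17 were under it in at least 1 alternative, and none turned sign. The spike-in scaling and the count on every spot were chosen after seeing the data.

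With intensity-dependent loess the list medians that moved were TCA 0.00069, cell wall -0.16, general stress -0.059, glycolysis -0.32, heat shock -0.044, mitochondrial import -0.087, nitrogen catabolite 0.052, oxidative stress -0.22, phosphate 0.23, nuclear respiratory complexes -0.61 and retrograde 0.27. With quantile normalization they were TCA -0.019, cell wall -0.17, general stress -0.043, glycolysis -0.35, heat shock -0.012, hexose transporters 0.18, oxidative stress -0.24, phosphate 0.18 and retrograde 0.23. With normexp they were all mitochondrial frames -2.23, core frames -2.83, MATa -0.78, hexose transporters -0.040, beta-oxidation -0.998, ribosome biogenesis 0.47 and thiamine -0.41, and the MTF1 bound was -2.44. The offset of normexp raises dim levels and so shrinks bounds by construction. With no filter on dim probes MTF1 was -5.92, the core frames -6.33, MATalpha -0.27 and meiosis -0.33. Without saturated probes the core frames were -3.99, heat shock 0.17 and oxidative stress -0.63. With the series values MTF1 was -3.57, all mitochondrial frames -3.38 and core frames -4.06. With genes well above background on both arrays alone, all mitochondrial frames were -5.79 and core frames -10.23, from 2 genes and 1 gene. For the shifts under loess and quantile normalization the cause was not tested. A gene saturated on both arrays holds a ratio set by the saturation limit and the scaling, such as -0.31 for CIT2. Leaving saturated probes out removes such values from the list medians, but their share of each shift was not tested. Background limits the dim genes, with the lowest probe well above background at 10.1 units in the wild type and 39.8 units in the mtf1 deletion. With 1 array per group no array could be left out. No paired analysis was possible because each group has 1 array.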

Other observations

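The lists of this part were chosen after their values were seen, and so were the tests on growth state, array sensitivity and the chromosomal region. The remaining tests were set before their results were seen. Among genes of glucose sensing and repression, 6 of 10 were at least 2-fold higher in the mtf1 deletion and none at least 2-fold lower. Their median was 2.84-fold higher. No rank among random lists is given for these lists, since members had been seen before the lists were made. The repressor genes NRG2 at 2.48, MIG2 at 2.41, MIG1 at 2.31 and NRG1 at 2.01 were higher, as was HXK2. Of 19 amino acid permease genes, 6 were at least 2-fold higher and 2 at least 2-fold lower, with a median of 0.66. After DIP5 came the branched-chain permeases BAP2 at 2.23 and BAP3 at 2.09 and the glutamine permease GNP1 at 1.39, while MMP1 and AGP3 were lower. Of 6 genes of the mitochondrial contact site complex, 3 were at least 2-fold lower, namely MIC60, MIC19 at -1.44 and MIC27 at -1.02, with a median of -0.74. MIC27 was under 2-fold with intensity-dependent normalization and with normexp. The 37 translation factor genes had a median of -0.03, positive with intensity-dependent normalization or without saturated probes.

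The cytosolic ribosomal protein genes were higher in the mtf1 deletion, at a median log2 ratio of 0.69, or 0.71 with the arrays scaled on spike-in controls. Coding length, probe GC content and signal level do not account for this, since against the 50 other genes nearest in all 3 properties the list kept a median excess of 0.78, where the central 95% of random lists ran from -0.13 to 0.16. An earlier growth state of the mtf1 deletion culture at harvest may be the source, and it cannot be told apart from an effect of the deletion with 1 culture per strain. The general stress list, which would be lower in such a culture, had a median of -0.29, inside its range of -0.40 to 0.06, and the cyclin and S-phase list, at -0.23, also lay inside its own. The same doubt holds for glucose-regulated genes such as HXT2, ADH2, FBP1 and the repressor genes. With 1 culture per strain it also holds for the other nuclear lists outside their range of random lists. Among these were ribosome biogenesis at 0.65, beta-oxidation at -1.15, the nuclear respiratory complexes at -0.74 and the proteasome at -0.74. An effect of the deletion stays open and untested for all of them.

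The mitochondrially encoded transcripts were near background in the mtf1 deletion, on the array with the noisier background. Lower sensitivity of that array does not account for their loss, since 0% of the 4220 nuclear genes as bright as ATP8 or brighter in the wild type, MTF1 left out, were not well above background in the mtf1 deletion, against 7 of the 9 mitochondrial frames that bright. For those 7 frames, loss of mitochondrial DNA, loss of its transcription and a change in the tails by which these transcripts are primed all stay open, since these arrays hold no measure of the DNA or of the tails. OLI1 at 62.7 units and Q0017 at 218 units remained well above background in the mtf1 deletion by their flags. OLI1 there lay below the brightest negative control spot, at 87.1 units. Whether the probes of OLI1 and Q0017 take up other RNA was not checked. Their signals therefore do not decide between loss of the DNA and loss of its transcription.

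TAF7, which lies next to MTF1, was higher at 2.37, a ratio that 41 genes including TAF7 reached or passed. The other 14 TFIID genes were not higher together, with a median of -0.087 and a highest value of 0.55. The region was not higher as a whole either. The other 8 measured genes within 5 positions of MTF1 had a median of -0.045 and a highest value of 0.95. That median pools both sides of MTF1, so it cannot exclude a change on 1 side. On the TAF7 side ORA1 had -0.90, MRPL44 -0.18, MRE11 -0.64 and UBP8 -0.26. The next genes on the far side, RRP5 at 0.95, RPS10B at 0.93 and PEP5 at 0.78, were also higher, and the first pair of these belongs to ribosome groups. An effect of the deletion at the MTF1 locus on TAF7 stays a candidate explanation, as does an effect of the missing protein. These arrays tested neither.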
